A study of Mus musculus with 4 samples.

How the data were processed

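Replication timing was measured in mouse embryonic fibroblasts in 4 groups, control, KO, non-induced and induced, with 1 array of 2 colours in each. Per the labels' protocols, cells took up BrdU (50 µM) for 1 hour, 80000 cells were sorted into an early and a late S phase fraction, BrdU-labelled DNA was immunoprecipitated and amplified genome-wide, and early DNA was labelled with Cy3 and late DNA with Cy5. Dyes were not swapped on any array, so a dye effect cannot be separated from timing on an array, although it cancels in differences between arrays as far as it is the same on each. The labels give the cell line different numbers in different fields. They describe deletion of the floxed allele by 4-hydroxytamoxifen (1 mM, 24 hours), give that deletion as the genotype of the KO array, and do not say how the induced cells were induced.

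Per the file headers, the arrays were read with Agilent Feature Extraction 11.5.1.1, while the submitters' processing notes name version 9.1. Per the file headers, the processed signal of each channel is an intensity after background subtraction and detrending, scaled by 1 linear dye factor per channel and array, with no lowess term. Dye factors were 4.75 to 6.47 for green and 1.77 to 4.02 for red. The deposited log10 ratio is late over early, and the deposited value table of the series held exactly equal log10 values, with no tolerance, in all 180880 spots of each array. After turning its sign, the deposited log10 ratio matched that of the processed signals within 1e-06 in 174068 to 174255 of 174305 genomic spots per array. The median log10 value per array was 0.0061 in control, -0.021 in KO, -0.0044 in non-induced and -0.015 in induced cells. Per the file headers, the other columns used are flags of spot quality with values of 0 or 1. Probe coordinates are those of the files, on mouse build mm9.

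Timing was computed as log2 of early over late processed signal. The 6575 control spots and spots with a non-uniformity or population outlier flag (154 to 447 per array) were left out, spots of a probe were averaged, and each array was centred on its autosomal median. No loess or quantile step was applied. Of 170183 probes on autosomes and X, 169660 were usable on all arrays, with a median spacing of 10879 bp. Probes were averaged in non-overlapping windows of 200 kb with at least 5 usable probes. A window was called later or earlier when its difference was at least 0.25 of the distance between the 10th and 90th percentile of windows on the reference array (0.45 log2 for KO and 0.52 for induced) and at least 3 times its standard error over probes. Called windows of one direction less than 1 Mb apart were merged into regions, and the 12 regions with the largest mean size per direction and comparison were named by coordinates. Intervals come from 1000 resamplings of chromosomes. Groups, comparisons, the calling rule and most alternatives were fixed before the data were examined.

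Precision is limited by the single array per group. Within an array, 1000 probes were printed 5 times, and the median SD of their log2 ratios was 0.16 in control, 0.16 in KO, 0.13 in non-induced and 0.15 in induced cells. The spread of log ratios between neighbouring probes that the scanner software reports was 0.42, 0.48, 0.48 and 0.55 in the same order, outside the range the software accepts for copy number work. Saturated spots, 11 to 28 per array, were kept. Each comparison lies within 1 slide; slide and cells cannot be told apart between non-induced and control.

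The calling step was tested on simulated data with the probe noise of each comparison. With 200 changed windows, 92.0% of those changed by 0.7 and 99.0% of those changed by 1.0 were recovered for KO, and 87.0% and 99.0% for induced, while 0.195% and 0.042% of unchanged windows were called. Multiplying a whole array by 1.3 called 3.66% of windows in the KO simulation and 3.35% in the induced one, and 0.083% and 0.033% after scaling arrays to the same spread. The measured spread of KO was 1.43 times that of control, and simulated noise was independent between probes. These shares therefore set no upper bound on what a scale factor can call in the data.

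Alternatives covered background correction (normexp with offset 50, planned on mean and run on raw median signals, so that the detrending and dye factors of the processed signals were left out too), loess within arrays, scaling, quantile normalization, the deposited value table, window size, probe number, dim and flagged probes, odd and even probes, chromosome X, thresholds, trends and the reference array. The files used here pair probes with coordinates on mm9, and the gene table at hand is of another build, so genes were not placed: 25 gene lists fixed beforehand and the targeted gene itself were not analysed here. GC content was not analysed here. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.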

Results

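Replication timing was measured in mouse embryonic fibroblasts, connective tissue cells cultured from mouse embryos, with 4 arrays of 2 colours each. Cells labelled with the nucleotide analogue BrdU were sorted into an early and a late S phase fraction, and the newly made DNA of both fractions was hybridised to the same array. Timing is the log2 ratio of early over late signal, so that a higher value means earlier replication. The groups were a control, a Suv4-20h knockout (KO) whose labels state a deletion of the floxed Suv4-20h1 allele, a non-induced and an induced inducible Suv4-20h mutant, with 1 array in each group. Suv4-20h enzymes are histone methyltransferases that act on histone H4 and are associated with heterochromatin. The control and KO arrays lay on 1 slide, and the non-induced and induced arrays on another. Each array held 174305 genomic spots, which gave 12000 windows of 200 kb with a median of 15 probes. Median signal above local background was 140 to 204 in the early channel and 220 to 434 in the late channel, and 89.1 to 94.9% of autosomal spots were well above background in both channels. With 1 array per group, no spread between cultures was measured and no test between conditions was made. Standard errors below are over probes within a region, and intervals resample chromosomes, so they cover variation along the genome only.

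All arrays showed alternating early and late domains. Chromosome 11 had the highest mean timing on every array, at 0.23 in control, 0.10 in KO, 0.18 in non-induced and 0.15 in induced cells. Chromosome X had the lowest, at -0.38, -0.66, -0.59 and -0.995 in the same order, and chromosome 3 was the lowest autosome, at -0.23, -0.45, -0.26 and -0.52. The distance between the 10th and 90th percentile of windows was 1.81 in control, 2.31 in KO, 2.07 in non-induced and 2.70 in induced cells. Relative to the autosomal probe median, the 10th percentile lay at -0.93, -1.39, -1.14 and -1.61, and the 90th at 0.88, 0.92, 0.93 and 1.09. The median window itself lay at -0.16, -0.39, -0.26 and -0.51. On which side the range widened therefore depends on the centre chosen. Across windows, which are not independent replicates, non-induced and induced timing correlated most closely (Pearson's r = 0.96), and KO and non-induced timing least (r = 0.83). Control and KO timing had r = 0.84.

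The first comparison was of KO with control cells, which may differ in more than the deletion of Suv4-20h1, as given below. Windows of late and middle timing had lower values on the KO array, although the latest quintile was at 0.023 once arrays were scaled to the same spread. The lowest mean difference among merged regions was on chromosome 12 from 46400001 to 50200000, where timing was 0.05 in control and -1.26 in KO cells, a difference of -1.32 ± 0.07 (SE over 135 probes). On chromosome 1, the region from 109000001 to 119400000 fell by 1.22 on the log2 scale, from -0.01 in control to -1.23 in KO cells, over 43 called windows. In total, 2658 windows (22.15%, 531.6 Mb) were later and 967 windows (8.06%, 193.4 Mb) were earlier in KO than in control cells. In these later windows, mean early signal relative to its autosomal median was -0.29 in control and -1.16 in KO cells. Mean late signal was 0.02 and -0.06, so on these means the lower ratio came from the early channel. Arrays were centred on probes, and the median window difference was -0.16 (-0.11 with arrays scaled to the same spread). This offset tips calls towards later, and no counts were made with windows centred on their own median.

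The later windows merged into 500 regions, of which 89 held 10 or more called windows. The longest, of 12.6 Mb, lay on chromosome X from 107200001 to 119800000, with timing of -0.10 in control and -1.17 in KO cells. Total signal on X also differed between these arrays, as given below, which limits what regions on X can show. Besides the regions above, the 12 later regions of largest size included chromosome 1 from 100600001 to 107200000 (0.08 in control, -1.17 in KO), chromosome 16 from 78800001 to 84400000 (-0.21 and -1.42), chromosome 2 from 39600001 to 43800000 (0.16 and -1.02) and chromosome 3 from 42400001 to 49000000 (-0.17 and -1.31). Chromosome 12 held another pair, from 64400001 to 65400000 (0.15 and -1.07, 16 probes) and from 66600001 to 70200000 (0.09 and -1.12). The remaining ones were chromosome 9 from 67800001 to 69400000 (0.51 and -0.69), chromosome 8 from 51200001 to 54600000 (-0.16 and -1.35), chromosome 15 from 71200001 to 72000000 (0.01 and -1.14) and chromosome 18 from 73400001 to 73600000 (-0.79 and -1.94, 5 probes). The non-induced array lay between control and KO in all 12: KO minus non-induced was -1.04 to -0.16, and non-induced minus control was -0.99 to -0.10. This follows in part from choosing the regions by KO minus control, and the non-induced array lay on another slide. Of all later windows, 2026 were already below 0 in control cells, and 554 crossed from 0 or above to below 0.

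**Figure D1:**
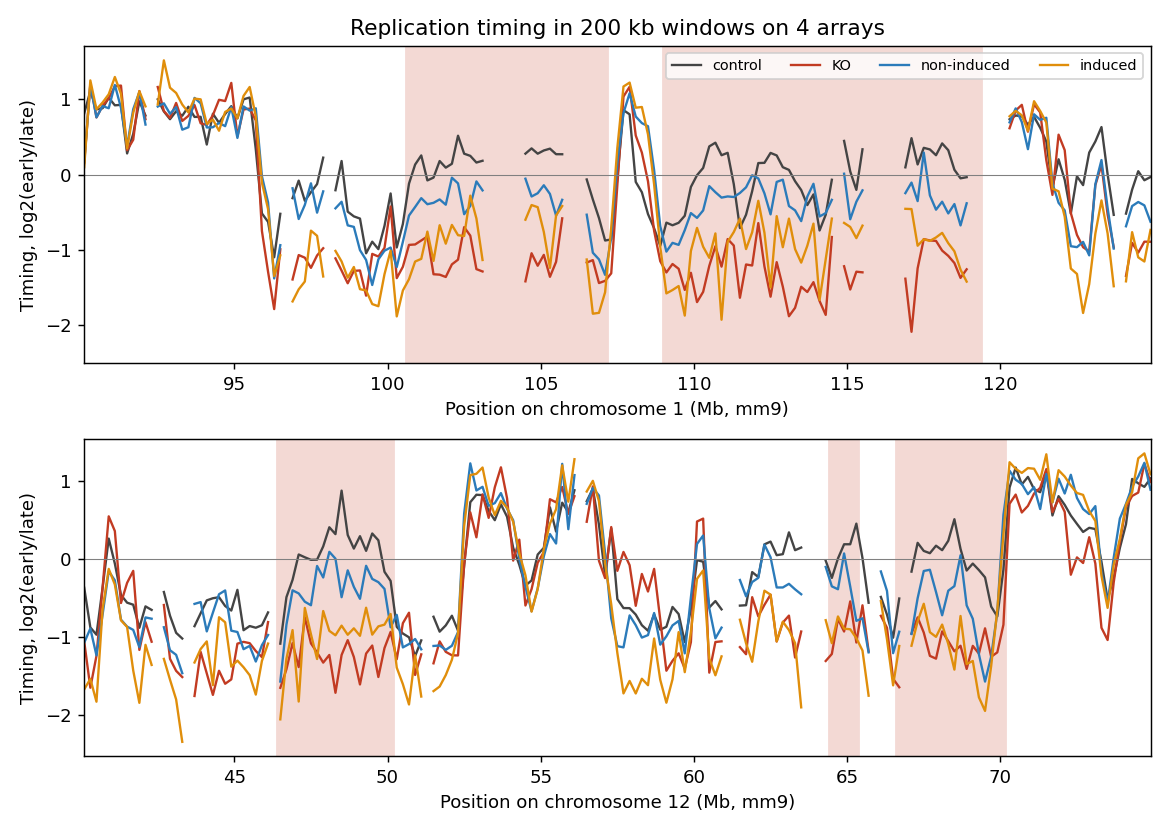
Timing in 200 kb windows (log2 early over late, vertical axis) along parts of chromosomes 1 and 12 (Mb, mm9) on the 4 arrays, with shading over regions among the 12 largest later regions of KO against control; line breaks mark windows with too few probes. In the shaded region of chromosome 1 from 109000001 to 119400000, mean timing over called windows was -0.01 in control, -0.41 in non-induced, -1.02 in induced and -1.23 in KO cells.

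Earlier regions were shorter: 377 were found, 5 of them with 10 or more called windows. The largest difference was on chromosome 1 from 87600001 to 87800000, at 1.299 ± 0.15 (SE over 19 probes), with timing of -0.66 in control and 0.64 in KO cells. Chromosome 8 held 3 of the 12 earlier regions of largest size, from 45600001 to 47000000 (-0.59 in control, 0.57 in KO), from 25400001 to 25800000 (-0.33 and 0.67) and from 35400001 to 36600000 (0.06 and 1.06). Chromosome 9 held another 3, from 95200001 to 96000000 (-0.35 and 0.84), from 75400001 to 76000000 (-0.28 and 0.69) and from 89800001 to 90200000 (-0.90 and 0.06). Chromosome 4 also held 3, from 153400001 to 153600000 (-0.61 and 0.62), from 3400001 to 3800000 (-0.46 and 0.69) and from 19600001 to 19800000 (-0.91 and 0.14). The last were chromosome X from 19400001 to 20200000 (-0.64 and 0.52) and chromosome 14 from 105400001 to 106600000 (-0.58 and 0.41). KO timing was above non-induced timing in all 12, by 0.16 to 1.15. Non-induced timing was itself above control in 11 of the 12, by up to 1.04. The exception was the region of chromosome 4 starting at 19600001, at -0.11 ± 0.13 (SE). Both counts follow in part from choosing the regions by KO minus control.

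Ranked by the mean timing of the non-induced and induced arrays, the latest quintile of windows had a mean KO minus control difference of -0.33 (95% interval -0.37 to -0.29), the next -0.41 and the middle one -0.30, while the fourth had 0.07 and the earliest 0.03; with the arrays scaled to the same spread these were 0.023, -0.12, -0.16, -0.055 and -0.22, so that the latest, the fourth and the earliest changed sign. The latest minus the earliest quintile was -0.36 (-0.39 to -0.32); after that scaling it turned to 0.24, and with quantile normalization to 0.096. Chromosome 16 had the lowest chromosome mean, -0.29 ± 0.49 (SD over 457 windows), and chromosomes X, 14, 1, 12 and 6 followed at -0.28 to -0.27. Chromosomes 13 and 19 stood near 0, at -0.00096 and -0.022, and were the only chromosomes with more earlier than later windows: 14.7% earlier and 11.2% later on chromosome 13, and 13.0% and 10.1% on chromosome 19.

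Y chromosome probes were well above background in both channels for 107 of 122 probes on the KO array and 50 on the control array, and X probes had lower total signal on the KO array by a median of -0.47, below the range of the autosomes (-0.24 to 0.28). All KO minus control values on X may therefore reflect different sex chromosomes, which cannot be told apart here from the deletion. Cells from different embryos could also differ on autosomes, which was not tested and which leaving out X does not address. Without X, 2483 windows were later and 924 earlier. Later and earlier windows numbered 1717 and 901 with normexp on raw median signals, 1498 and 760 once arrays were scaled to the same spread, 1143 and 1094 with quantile normalization, 1845 and 1395 with the intensity trend of the difference removed, and 1032 and 1496 with its linear trend on timing removed, against 2658 and 967; the 12 largest later regions then had differences of -0.86 to -0.44 with normexp and -0.99 to -0.56 after scaling. The same rule called 1287 windows later and 987 earlier between the non-induced and control arrays, which differ in slide as well as in cells. These numbered 865 and 843 once arrays were scaled to the same spread, and 823 and 1140 with the linear trend on timing removed.

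**Figure D2:**
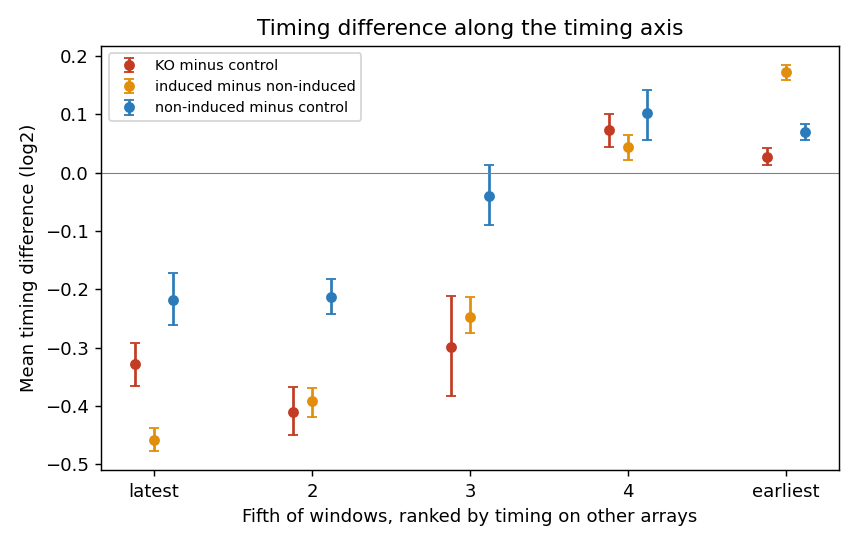
Mean timing difference (log2, vertical axis) in quintiles of windows ranked from latest to earliest by arrays other than both compared ones (for non-induced minus control, by KO and induced), with 95% intervals from resampling chromosomes. The latest quintile lay at -0.33 for KO, -0.46 for induced and -0.22 for non-induced cells against their references; when arrays were scaled to the same spread, the KO value of the latest quintile turned to 0.023 and the induced value of the earliest quintile to -0.052.

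The second comparison was of induced with non-induced mutant cells, and it asks how timing differs upon induction. Late domains had lower values on the induced array, while early domains were slightly higher, a direction that turned when arrays were scaled to the same spread. The longest later region, of 9.8 Mb on chromosome 4 from 21600001 to 31400000, had timing of -0.62 in non-induced and -1.40 in induced cells, a difference of -0.78 ± 0.04 (SE over 250 probes). On chromosome X, mean timing was -0.59 in non-induced and -0.995 in induced cells, with 20.0% of its windows later and 0 earlier, all without scaling. In all, 1434 windows (11.95%, 286.8 Mb) were later and 56 (0.467%, 11.2 Mb) earlier in induced cells. The median window difference was -0.13 (-0.070 after scaling), which tips these calls towards later too.

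The later windows merged into 409 regions, of which 15 held 10 or more called windows. The 12 of largest size were short and rested on 5 to 36 probes each. The largest, chromosome 1 from 29800001 to 30000000, had a difference of -1.76 ± 0.52 (SE over 5 probes), and a window nearby on chromosome 1, from 28600001 to 28800000, had -1.11. Better measured were chromosome 12 from 47000001 to 48400000 (-0.11 in non-induced, -1.27 in induced, 26 probes), chromosome 6 from 67800001 to 69000000 (-0.55 and -1.66, 36 probes), chromosome 11 from 90800001 to 92800000 (-0.64 and -1.73, 31 probes) and chromosome X from 60600001 to 62000000 (-0.41 and -1.45, 24 probes). The others were chromosome 3 from 7800001 to 8000000 (-1.21), chromosome 7 from 59800001 to 60600000 (-1.13), chromosome 1 from 114000001 to 114200000 (-1.11), chromosome 2 from 133200001 to 133400000 (-1.07), chromosome 8 from 7000001 to 7600000 (-1.04) and chromosome 9 from 90600001 to 91400000, with a difference of -0.99. Of the later windows, 1399 were already below 0 in non-induced cells and 33 crossed from 0 or above to below 0.

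The 12 earlier regions of largest size were single windows, with differences of 0.63 to 0.90; after scaling to the same spread 4 of the 12 were still called, and over well measured probes the differences were 0.28 to 0.65. They began with chromosome 2 from 27600001 to 27800000, which rose from -0.18 to 0.72 (15 probes), chromosome 4 from 105400001 to 105600000 (-0.25 and 0.54, 6 probes) and chromosome 17 from 84400001 to 84600000 (0.36 and 1.15, 9 probes). Over well measured probes, that of chromosome 2 was 0.45 and that of chromosome 17 was 0.28. Chromosome 6 from 60600001 to 60800000 went from -0.16 to 0.52 (16 probes); its difference of 0.68 was 0.36 with the deposited log ratios, 1.14 over odd and 0.22 over even probes. Chromosome 14 from 78400001 to 78600000 went from -0.10 to 0.58. The others lay on chromosome 9 from 65200001 to 65400000, chromosome 17 from 7200001 to 7400000, chromosome 5 from 143600001 to 143800000, chromosome 3 from 88200001 to 88400000 (0.31 over odd and 0.94 over even probes), chromosome 11 from 94800001 to 95000000, chromosome 1 from 155800001 to 156000000 and chromosome 7 from 117800001 to 118000000.

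In quintiles ranked by the mean timing of control and KO, induced minus non-induced timing was -0.46 (95% interval -0.48 to -0.44) in the latest quintile, -0.39 and -0.25 in the next ones, 0.04 in the fourth and 0.17 (0.16 to 0.18) in the earliest; with arrays scaled to the same spread all were below 0, at -0.091, -0.10, -0.11, -0.060 and -0.052. The latest minus the earliest quintile was -0.63 (-0.65 to -0.61), and it was -0.039 with arrays scaled to the same spread. After chromosome X, at -0.40 ± 0.29 (SD over 686 windows), chromosome 3 had the lowest chromosome mean, at -0.26, and chromosomes 11 and 19 stood closest to 0, at -0.033 and -0.022. Chromosomes X and 3 also had the lowest mean timing on the non-induced array, at -0.59 and -0.26, and chromosome 11 the highest, at 0.18. Chromosome means were not computed after scaling, so the part of a scale factor in this order was not tested.

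The early channel was well above background in 77.1% of spots in the latest quintile of windows on the induced array, against 90.8% on the non-induced array. Later and earlier windows numbered 738 and 12 over probes well above background on all arrays, 220 and 8 with arrays scaled to the same spread, 145 and 19 with quantile normalization, 281 and 52 with normexp on raw median signals, 907 and 176 with loess within arrays, 683 and 235 with the intensity trend of the difference removed, and 84 and 80 with its linear trend on timing removed, against 1434 and 56; the 12 largest later regions then had differences of -0.51 to -0.25 with normexp and -1.18 to -0.42 after scaling. Against the control array in place of the non-induced one, 3564 windows were later and 1109 earlier in induced cells.

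**Figure D3:**
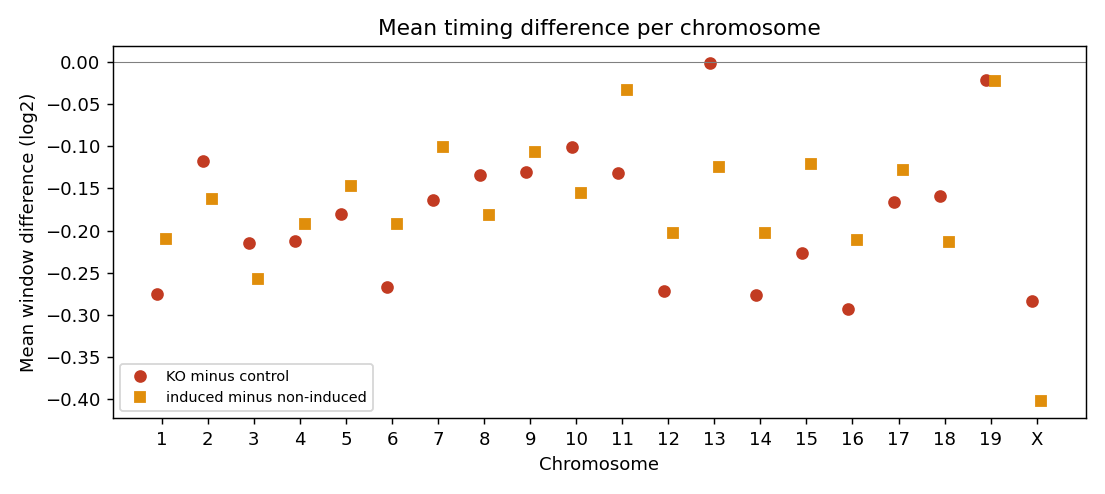
Mean timing difference over windows (log2, vertical axis) for each chromosome, as circles for KO minus control and squares for induced minus non-induced. Chromosome X had the lowest induced value, -0.40, and chromosomes 13 and 19 the KO values closest to 0. These means were not computed with arrays scaled to the same spread.

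Set side by side, the KO and induced differences, which share no array, went together mostly in windows of late and middle timing. In the 12 largest later regions of KO, induced minus non-induced timing was -0.63 to -0.091, with a median of -0.59 where windows of like timing (20 bins of the mean of all arrays) had -0.35. Of the 12, 10 lay below windows of like timing. After scaling to the same spread, the median was -0.30 against -0.11, 10 of the 12 lay below windows of like timing, and 1 of the 12 turned above 0. In the 12 largest earlier regions of KO, induced minus non-induced timing had a median of -0.033 where windows of like timing had -0.087 and all windows -0.13. Before and after scaling, 10 of these 12 lay above windows of like timing. In the 12 largest later regions of induced cells, KO minus control timing was -1.67 to -0.073, with a median of -0.91 against -0.42 in windows of like timing. Before and after scaling, 11 of these 12 lay below windows of like timing. Of the 12 largest earlier regions of induced cells, 8 lay below windows of like timing in KO minus control timing, with a median of -0.27 against 0.086 (-0.41 against -0.090 after scaling).

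Later in both comparisons were 786 windows, where 518 would be shared by chance within quintiles of timing, 318 regardless of timing, and at most 400 over 10000 rotations of one profile along the genome. After scaling to the same spread, 118 windows were later in both, where 34.0 would be shared by chance within quintiles. The 786 windows shared without scaling merged into 309 regions, and the values below are also without scaling. The regions with most shared windows, chosen after their values were seen, included chromosome 2 from 85600001 to 89200000, with -1.14 ± 0.06 (SE) in KO and -0.81 ± 0.05 in induced cells, and chromosome 14 from 107200001 to 110800000, with -1.60 ± 0.08 and -0.90 ± 0.08. Others were chromosome X from 41600001 to 44000000 (-1.06 and -0.88) and chromosome 8 from 99000001 to 104000000 (-1.04 and -0.87). Earlier in both were 2 windows, where independent lists would share 4.51.

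Across the 12000 windows, which are not independent replicates, the differences had Pearson's r = 0.49 (95% interval 0.45 to 0.52) and Spearman's rho = 0.49, with r between -0.067 and 0.097 over the rotations. For scale, odd and even probes of a single comparison had r = 0.85 for KO and 0.70 for induced differences. Within quintiles of mean timing, r was 0.23 in the latest, 0.43 and 0.46 in the next ones, -0.049 in the fourth and -0.21 in the earliest. The correlation was 0.17 with normexp on raw median signals and 0.31 both with arrays scaled to the same spread and over probes well above background.

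**Figure D4:**
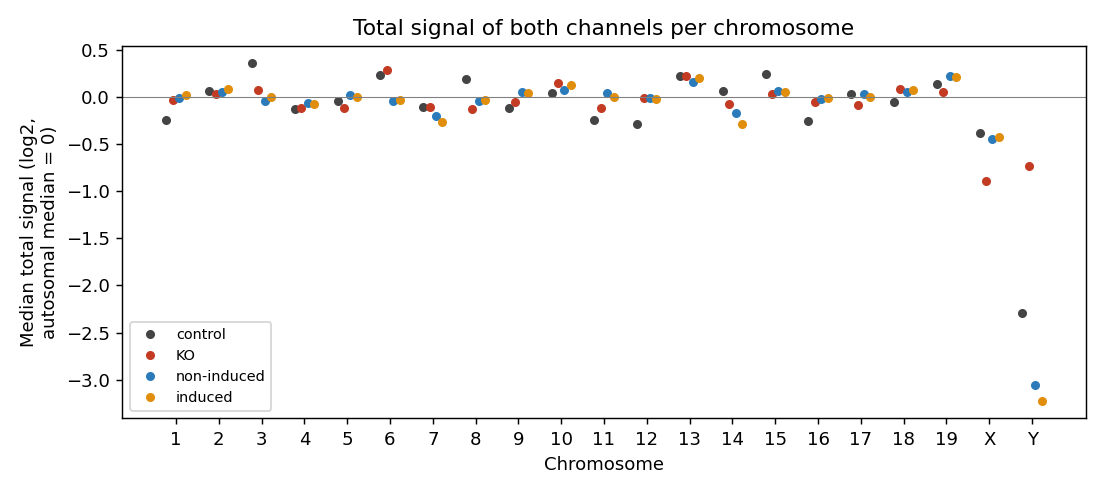
Median total signal of both channels (log2, autosomal median set to 0, vertical axis) for probes of each chromosome on the 4 arrays. On Y, the KO array stood at -0.73 and the others at -3.23 to -2.29; on X, the KO array stood at -0.89 and the others at -0.44 to -0.38.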

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

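The tests on Y and X signal and the scaling test of the shared windows were chosen after the results were seen. So were the limits of the tests on scaling and on dim probes of the timing range. Scaling, trend removal, normexp and well measured probes were planned as alternatives, while their combinations were not. The tests on timing position and dim probes of the shared windows were set beforehand. Y chromosome probes, which no comparison used, gave signal on the KO array: 107 of 122 were well above background in both channels, against 50 on the control, 53 on the non-induced and 41 on the induced array. A general rise in background is argued against as the source of the Y signal, by a measure changed more than once after values were seen. It takes the 200 autosomal probes nearest to each Y probe in signal on the non-induced array. Their share well above background was 63.6% in control and 48.6% in KO, a difference of -15.0 percentage points where Y probes differed by 46.4. Whether background itself rose cannot be read from this share. A swap of labels within the series cannot be told apart, since 1 bright array among 4 (highest other share of Y probes 43.4%) would be seen with or without one. A different sex chromosome complement of the KO cells may account for it: the X difference of -0.47 lies below every autosome (lowest -0.24). Different embryos of origin stay open, untested, beside Suv4-20h as a source of the timing difference.

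The timing range was wider in KO and induced cells than in their references, with spreads (median absolute deviation) 1.43 times that of control for KO and 1.31 times that of non-induced for induced cells. In KO, a single scale factor per array, as unequal enrichment of the fractions could give, is argued against as the whole cause of the later windows: 12.5% were later after scaling (95% interval over chromosomes 10.8 to 14.2), 8.60% with the linear trend on timing removed (where earlier windows were more numerous, 1496 against 1032) and 10.0% with scaling and well measured probes together, from 22.15%. The limit used was 5%, set after the results were seen. Between non-induced and control, 7.21% were later after scaling and 6.86% with the trend removed. Differences between single arrays can thus also leave windows above that limit. In induced cells, a scale factor stays open, since 1.83% were later after scaling but 0.70% with the trend removed, from 11.95%. Dim signal stays open there too: over the same 10379 windows, well measured probes left 738 of 1055 later windows, a ratio of 0.70, while normexp on raw signals left 0.20 of all later windows and removing the intensity trend left 683 of 1434. Both together left 0.453% in induced cells, which decides nothing, since low early signal on the induced array both makes a window later and removes its probes, and 1.26% with probes chosen on control and KO alone; an effect of Suv4-20h on the range was not tested.

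Later windows were shared between KO and induced cells. Position on the timing axis is argued against as the whole explanation: the overlap of 786 windows was 1.52 times (95% interval over chromosomes 1.43 to 1.60) the number expected within quintiles of timing, and 1.47 times within 50 bins. A scale factor is argued against too as the whole explanation, since after scaling 118 windows were shared where 34.0 were expected within quintiles, a ratio of 3.47 (2.94 to 4.22). The correlation was 0.31 after scaling (rotations -0.050 to 0.056), from 0.49. Rotations do not keep timing position, so they cannot exclude a shared dependence on timing that scaling leaves. Dim signal stays open. The correlation was 0.31 with well measured probes (0.27 to 0.35), above the limit of 0.5 of its value set beforehand. It was 0.44 with the intensity trend removed and 0.43 with loess. With normexp, which also took raw signals, it was 0.17, below that limit. An effect of losing Suv4-20h activity in both comparisons is a hypothesis that these 4 arrays leave open, along with clonal and culture differences, which were not tested.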

How the results depend on the processing

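Window counts, the KO and induced quintile contrasts, the correlation and the named regions were recomputed with 1 choice changed at a time. Normexp, as an exception, also took raw median in place of processed signals. Thresholds, the linear trend on timing and the reference array were changed for counts only. Window size, probe number and chromosome X were not changed for named regions. The combinations of well measured probes with scaling were chosen only after the results were seen. With the deposited value table, without outlier filtering, without chromosome X and with a threshold of 0.5, every count stayed within 1.5 times, and the contrasts and the correlation stayed within their chromosome intervals in the first 3 of these, where they were run. In the other settings, the values that moved further follow, and the cause was not tested unless given. Normexp on raw signals gave 1717 windows later in KO and 281 in induced, latest minus earliest quintiles of -0.084 for KO and -0.28 for induced, and a correlation of 0.17. Loess within arrays gave 907 later and 176 earlier in induced, a quintile contrast of -0.57 for induced and a correlation of 0.43. Scaling to the same spread gave 1498 later in KO, 220 later and 8 earlier in induced, quintile contrasts of 0.24 for KO, which is reversed, and -0.039 for induced, and a correlation of 0.31; 1177 of the 1498 and 216 of the 220 were also called without scaling. Quantile normalization gave 1143, 145 and 19, contrasts of 0.096, again reversed, and -0.094, and a correlation of 0.34. Windows of 100 kb gave 1502 earlier in KO, 145 earlier in induced, an induced contrast of -0.59 and a correlation of 0.37. Windows of 500 kb, which are fewer (5028), gave 1312 later (26.1%, a larger share than 22.15%) and 348 earlier in KO, 949 (18.9%, against 11.95%) and 5 in induced and 610 and 367 in non-induced, with -0.65 and 0.56. At least 10 probes, with 8488 windows, gave 1439 later in KO (17.0%), 875 in induced (10.3%) and 827 in non-induced, with -0.58 and 0.41. Probes well above background gave 738 later and 12 earlier in induced, contrasts of -0.26 for KO and -0.48 for induced, and a correlation of 0.31. Removing the intensity trend of the difference gave 683 later and 235 earlier in induced, -0.59 and 0.44. Odd probes, with 8673 windows, gave 1214 later in KO (14.0%), 608 in induced (7.01%) and 682 in non-induced, with -0.60 and 0.37; even probes gave 1198, 618 and 691, 652 earlier in non-induced, -0.60 and 0.38. A threshold of 0.15 of the range gave 1513 earlier in KO, 2302 later and 587 earlier in induced; one of 0.4 gave 1430 and 336, 377 and 1, and 453 and 310 in non-induced. Without the standard error rule 2231 were later in induced. Removing the linear trend on timing gave 1032 later and 1496 earlier in KO, 84 later in induced and 823 later in non-induced. Control in place of non-induced gave 3564 later and 1109 earlier in induced. Well measured probes and scaling together gave 1038 later in KO, 47 later and 5 earlier in induced; with probes chosen on control and KO alone, 142 were later and 7 earlier in induced. Named regions kept their direction in all 479 values computed, which follows in part from choosing them by size on the same arrays. After scaling, 2 of the 12 later and 10 of the 12 earlier KO regions kept all their windows called (11 and 12 kept at least 1), against 2 and 4 for induced (9 and 4). The earlier regions had differences of 0.63 to 0.99 in KO and 0.33 to 0.59 in induced with normexp, and of 0.68 to 1.11 and 0.26 to 0.59 after scaling. Gene list alternatives were not run. No array can be left out with 1 per group. No paired analysis was possible because each group has 1 array. Signal over background limits late windows of the induced array most.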

Other observations

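The observations here were all chosen after seeing the data. Centromere-distal chromosome ends had fewer later and more earlier windows than chromosome interiors. In the last 10 Mb covered, mean KO minus control timing was -0.05 ± 0.44 (SD over 954 windows) with 13.3% of windows later and 10.9% earlier, against -0.20 ± 0.50, 23.1% and 7.67% in interiors. In induced cells 9.12% were later and 1.05% earlier at distal ends, against 12.2% and 0.415% in interiors. Distal ends were later than the interior of the same chromosome in 3 of 20 chromosomes for KO and in 4 of 20 for induced cells. Distal ends were also earlier in control cells, at 0.03 against -0.08 in interiors. The first 10 Mb covered, near the centromere, gave -0.15 for KO, lower than the interior on 7 of 20 chromosomes, and -0.23 for induced cells, lower on 13 of 20.

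Differences extended over neighbouring windows. At a distance of 2 Mb, window differences still had r = 0.22 for KO and 0.32 for induced cells, against 0.054 for non-induced minus control. Timing itself lies in domains, and these values were not computed after scaling or trend removal. The part of a scale factor in them was therefore not tested.

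In windows later in KO, the channels were compared singly, each relative to its autosomal median. Mean early signal was -0.29 ± 0.53 (SD over 2658 windows) on the control array, -1.16 ± 0.81 on the KO array, -1.04 on the non-induced and -1.30 on the induced array. Mean late signal was 0.02 on the control, -0.06 on the KO, -0.41 on the non-induced and -0.26 on the induced array. Mean timing of these windows was -0.33 on the control, -1.17 on the KO, -0.56 on the non-induced and -1.04 on the induced array. Over windows of the 12 largest later regions of KO, mean early signal was -0.55 on the control, -1.45 on the KO, -1.39 on the non-induced and -1.75 on the induced array. Their mean late signal was -0.55, -0.28, -0.92 and -0.75 in the same order. The windows were chosen on control and KO, so the values of these arrays follow in part from the choice.

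Total signal of both channels also varied by chromosome, over the widest range of autosomes on the control array. Relative to autosomes, the control array stood at 0.36 on chromosome 3 and at -0.29 on chromosome 12, -0.25 on chromosome 16, -0.25 on chromosome 11 and -0.24 on chromosome 1. The non-induced array stood at -0.05 on chromosome 3, -0.01 on chromosome 12 and 0.05 on chromosome 11. Autosomal medians of the difference ranged from -0.36 to 0.36 for non-induced minus control and from -0.14 to 0.0074 for induced minus non-induced. Across windows, timing and total signal differences had r = 0.46 for KO and 0.0025 for induced cells.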
